A study of Mus musculus with 9 samples.

How the data were processed

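Total RNA of the olfactory bulb of 9 CD1 mice, 1 animal per day from E11 to E18 and 1 at birth (P0), was amplified in 2 rounds, labelled with biotin and hybridised to 1 Affymetrix mouse array each, per the labels. The deposited values were log2 expression levels per probe set, made by the authors with GCRMA, which corrects the background by probe sequence and normalises between arrays, per the submitters' processing notes. The version of GCRMA was not given in the sources used here, and the log2 scale was inferred from the range of the values and from that method. The table held 45101 probe sets on 9 arrays, of which 64 were controls. The number of arrays limits the precision of every value. No scaling was applied to the deposited values. Quantile normalization would have moved the median of an array by at most 0.0872 and median centring by at most 0.0595 log2 units.

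Of the probe sets, 34958 carried 1 gene name in the platform annotation, 932 several and 9211 none. Names were looked up by Entrez ID in a RefSeq gene table for 34754 probe sets, and 0 symbols changed. Probe sets that read log2 5 or more on at least 2 of the 9 arrays were kept (21724). Of these, probe sets with exactly 1 gene name were used, and for a gene with several the one with the highest mean over the arrays, which left 10864 genes. Probe sets with several names or none were left out of the comparisons, since they name no single gene, and are described in the closing section.

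Each gene was fitted against age in days with limma 3.58.1 in R 4.3.3 (linear model, moderated variance with a trend on the mean level, two-sided test of the slope, Benjamini-Hochberg over all genes tested, threshold 0.05). Ages were E11 as day 11 to E18 as day 18, and P0 was placed at day 19. The fit left 7 residual degrees of freedom (10.3 with the moderated variance), and the median residual standard deviation was 0.24 log2 units. Slopes are printed with their moderated standard error. Folds compare P0 with E11 with values under log2 5 set to 5, and are written as at least that fold where a value was under 5. Peaks and dips were called on the quadratic term of a fit with age and age squared, at the same threshold, where the fitted turning point lay inside the course and away from its ends. The size of a peak or dip is the fitted value at the turning point minus the mean of the fitted ends. Counts of 2-fold differences between consecutive ages used single arrays and no test.

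Gene lists were fixed before the data were examined and tested where at least 3 members were tested (33 lists), with camera from limma and a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. The lists were cell cycle, radial glia and neural progenitors, Notch pathway, proneural and intermediate progenitor genes, mitral and tufted cells, GABAergic interneuron lineage, synapse, axon growth and migration, astrocytes, oligodendrocyte lineage, olfactory ensheathing cells, olfactory sensory neurons and epithelium, meninges and mesenchyme, cartilage and bone, endothelium and vessels, red cells and globins, microglia and macrophages, skeletal muscle, surface ectoderm and respiratory epithelium, pigment cells, immediate early and stress genes, heterochronic regulators, ribosomal proteins, oxidative phosphorylation, Wnt, and FGF, BMP, Shh and retinoid signalling. The remaining lists were classes of transcription factors (zinc finger Zfp, homeobox, Sox and Fox, basic helix-loop-helix and Id, nuclear receptors, others) and their union. Transcription factors were compared with all other genes tested by Fisher's exact test, two-sided. Embryo sex was read from Xist and the Y-linked genes.

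Genes were named by a rule written before the data were examined. It took the 10 rising and 10 falling genes with the largest slopes past the threshold, leaving out clone names, the 8 rising and 8 falling transcription factors with the largest slopes, the 8 largest peaks and 5 largest dips. It further took the 2 to 4 members of each list with the largest slopes, other members needed to describe a list, and a set of marker genes of bulb cells. Of that set, 3 genes were not analysed here. Wif1, Lamb2, Mt1 and Slc16a1, and Neurod6 for its peak, were picked outside the rule, after their values were seen. Other probe sets were compared for genes taken by their slope, peak or dip, or as marker genes. They were not compared for the other list members named, such as Apoe and Id4, or for genes picked outside the rule. Among the genes compared, another probe set passed the filter for 56, and for 2 of them, Eomes and Rpl7l1, 1 such probe set had a slope of opposite sign.

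The procedure was tested on simulated data with the mean and the residual scatter of each of the 10864 genes on 9 arrays. Linear trends of 1, 2 and 4 log2 units over the course were recovered in 40.3%, 83.6% and 95.5% of changed genes, with 6 false calls among 152. Peaks and dips of these sizes were recovered in 56.7%, 86.6% and 97.0%, with 5 false calls among 165. A list of changed genes gave adjusted p = 2.53e-66, and 0 of 20 random lists were called. The scatter was drawn independently for each gene, so that the simulation cannot tell how camera treats lists of correlated genes. In each fit 67, 67 and 66 genes were changed by 1, 2 and 4 log2 units. In the data far more genes, 5125, had a linear trend. The threshold adjusted over all genes was therefore stricter in the simulation, and the shares recovered need not hold for the data. Simulated peaks and dips carried no linear trend, while 363 of the 476 peaks in the data also rose. Alternatives planned before the data were examined were no filter, a stricter filter and a filter on the mean, quantile normalization, median centring, the mean of probe sets, leaving out probe sets that can match several transcripts by their ID, a variance model without trend, P0 at day 20, embryo sex as a covariate, exact rank correlation, the linear term of the quadratic fit, other thresholds and leaving out each array in turn. Added after the data were seen were a floor of 5 for all values, a fit from E13 to P0, a stricter meaning of peaks and dips, and the transcription factors without the Zfp genes, which were then counted among the other genes. The closing section gives the effects of these alternatives.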

Results

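Levels of messenger RNA were measured on oligonucleotide arrays in the olfactory bulb, the forebrain structure that receives the input from the nose, of 9 CD1 mice. The mice were taken once a day from embryonic day 11 (E11) to E18 and at birth (P0). Each age was represented by 1 array made from 1 animal, so that no age had a replicate and the error of every trend came from the scatter of the 9 animals around it. The series concerned transcription factors of progenitor cells that reside in the bulb, and the comparisons asked which genes followed age. The median log2 level over all probe sets lay between 4.08 at E11 and 4.23 at E16. Xist, the RNA of the inactive X chromosome, read between 13.42 and 13.98 at E11, E12, E15 and P0, where the mean of the Y-linked genes was at most 2.78. At E13, E14, E16, E17 and E18, Xist read at most 2.76 and the mean of the Y-linked genes was at least 8.79, so that the sexes were spread unevenly over the ages. The difference between the 3' and 5' probe sets of actin, a sign of RNA quality, lay between 1.48 and 1.90 log2 units, and that of Gapdh between 1.55 and 2.12.

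The steepest rises with age included genes known from glia, from the brain coverings and from mature neurons. Ptgds, the prostaglandin D synthase made by the meninges, rose by 1.18 ± 0.17 log2 units per day (standard error, n = 9 arrays) and read 7.37 at E11, 3.59 at E12 and 13.74 at P0. Bcan, a proteoglycan of glial and perineuronal matrix, rose by 1.03 ± 0.070 per day and was at least 48.1-fold higher at P0 than at E11. Cpne6, a calcium-binding protein of brain neurons, rose by 1.04 ± 0.16 (at least 117-fold), and Npy, a neuropeptide also made by ensheathing glia, rose by 1.02 ± 0.14 (at least 142-fold). The other genes among the 10 with the largest rising slopes were Gdf10, Ogn (1.11), Slc6a13 (1.08), Gda (1.06), Gjb6 (1.03) and Slc26a7 (1.01). Ogn encodes a small proteoglycan of connective tissue, Slc6a13 a transporter of GABA found in the meninges, Gda guanine deaminase and Gjb6 connexin 30. Over all genes, 2743 of the 10864 tested rose and 2382 fell at an adjusted p of 0.05 from limma, and 5739 did not pass. A change of at least 2-fold over the course was fitted for 2077 of the rising and 1240 of the falling genes. With the E11 and E12 arrays left out, an alternative chosen after the data were seen, 1529 genes rose and 1193 fell.

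Embryonic globins were among the steepest falls. Hbb-y, the epsilon globin of primitive red cells, had the steepest of all (adjusted p = 6.28e-05) and read 15.52 at E11 and 2.90 at P0, at least 1469-fold lower. Hba-x and Hbb-bh1, the other embryonic globins measured by a probe set of their own, had slopes of -1.42 ± 0.18 and -1.36 ± 0.24. Hmga2, a chromatin protein of embryonic stem and progenitor cells, had a slope of -1.29 ± 0.080 (adjusted p = 4.99e-06) and read 12.87 at E11 and 3.92 at P0, at least 234-fold lower. Isl1, a LIM homeobox factor of ventral forebrain and other early neurons, read 10.14 at E11 and 2.34 at P0. The remaining genes of the 10 steepest falls were Stat4 (-0.82), Neurog1 (-0.72), Dct (-0.72), Fndc3c1 (-0.71) and Nhlh1 (-0.64). Dct encodes an enzyme of melanin synthesis and is also expressed in early forebrain progenitors, while Neurog1 and Nhlh1 are basic helix-loop-helix factors of newborn neurons.

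Genes of cell division fell. All 34 tested members of the cell cycle list fell, and all 34 did so when adjusted over the list alone. Mki67, the antigen of cycling cells, had a slope of -0.32 ± 0.021 (adjusted p = 6.07e-06) and read 13.29 at E11 and 10.56 at P0, 6.61-fold lower. The steepest members were Cenpe, a kinetochore motor (-0.47 ± 0.033), the checkpoint kinase Bub1b (-0.47 ± 0.027), and the mitotic kinases Plk1 (-0.46 ± 0.027) and Aurka (-0.46 ± 0.024). The median change of the list over the course was -3.01 log2 units. Camera, a test of the list against the other genes, gave adjusted p = 3.08e-25 with a preset correlation between genes, and adjusted p = 0.184 with an estimated correlation. The median of the red cell list was 11.32 at E11 and 5.41 at P0 on the same arrays.

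Most genes of radial glia and neural progenitors fell. Of 21 tested members 2 rose, 18 fell and 1 did not pass, and 2 rose and 18 fell when adjusted over the list alone. Besides Hmga2, the steepest were Nr2e1, an orphan nuclear receptor of neural stem cells (-0.60 ± 0.056), Sox3, a progenitor factor of the SoxB1 group (-0.58 ± 0.070), and Otx2, a homeobox factor of the early forebrain (-0.57 ± 0.076). Pax6, a factor of forebrain progenitors and of some bulb interneurons, had a slope of -0.25 ± 0.020 (adjusted p = 1.43e-05) and read 11.37 at E11 and 9.46 at P0. Sox2, a general progenitor factor, had a slope of -0.11 ± 0.038 (adjusted p = 0.0356), and this call ended without the E11 (adjusted p = 0.153), E12 (0.112), E16 (0.0526) or E18 array (0.0776). It also ended with embryo sex in the fit (adjusted p = 0.0650), with P0 at day 20 (0.0525), without a filter (0.0707), by exact rank correlation (0.236) and from E13 to P0 alone (0.850). The 2 members that rose were Slc1a3, a glutamate transporter kept by astrocytes (0.33 ± 0.056), and Fabp7, a lipid-binding protein shared with ensheathing glia (0.11 ± 0.018). Sox1 had a slope of -0.072 (adjusted p = 0.117) and did not pass, except without the P0 array (adjusted p = 0.0164). The list as a whole passed downward (adjusted p = 1.00e-06), but not when the correlation was estimated (adjusted p = 0.304 with an estimated correlation).

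Proneural factors of newborn neurons fell with age. Neurog1 read 8.43 at E11, 9.17 at E12 and 3.07 at P0 (slope -0.72 ± 0.064, adjusted p = 2.55e-05). Neurog2, the related factor of glutamatergic lineages, had a slope of -0.43 ± 0.060 and read 11.51 at E11, 12.47 at E12 and 8.80 at P0. Of 22 tested members of the list of proneural and intermediate progenitor genes, 0 rose, 15 fell and 7 did not pass, and 0 rose and 15 fell when adjusted over the list alone. Nhlh1 (-0.64 ± 0.073), Neurod4 (-0.47 ± 0.086) and Nhlh2 (-0.43 ± 0.040) were among those that fell. Eomes, the T-box factor of intermediate progenitors and of mitral and tufted cells, stayed without a linear call (slope 0.044 ± 0.042, adjusted p = 0.416), and another Eomes probe set had a slope of -0.020. Neurod1 (0.080, adjusted p = 0.123) and Neurod2 (-0.045, adjusted p = 0.665), factors of differentiating neurons, did not pass either, although the Neurod1 call was gained without the E18 array (adjusted p = 0.0394) and for the linear term of the fit with age squared (0.0299). Camera gave adjusted p = 1.30e-05 for the list and adjusted p = 0.184 with an estimated correlation.

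Genes of Notch signalling, which keeps progenitors from differentiating, went both ways. Of 20 tested, 6 rose, 11 fell and 3 did not pass, and 7 rose and 11 fell when adjusted over the list alone. Those that fell included the ligand Dll3 (-0.42 ± 0.078), the modifier Mfng (-0.40 ± 0.039) and Dll1 (-0.38 ± 0.032). The target genes Heyl, a gene of vessel mural cells (0.54 ± 0.10), and Hey2 (0.47 ± 0.074) rose. The list did not pass (adjusted p = 0.134), nor did it with the correlation estimated (adjusted p = 0.421 with an estimated correlation).

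Genes of mitral and tufted cells, the output neurons of the bulb, mostly rose. Tbx21, a T-box factor specific to these cells in the brain, had a slope of 0.82 ± 0.079 (adjusted p = 4.16e-05) and read 2.40 at E11 and 9.28 at P0, at least 19.5-fold higher. Cdhr1, a cadherin of mitral cells, rose by 0.87 ± 0.15 (177-fold), Thy1, a surface protein of projection neurons, by 0.89 ± 0.11 and Tshz2, a zinc finger homeobox factor, by 0.64 ± 0.10. Tbr1, a T-box factor of newborn glutamatergic neurons, fell with a slope of -0.19 ± 0.046 (adjusted p = 0.00614) and read 11.57 at E11, 12.11 at E12 and 10.29 at P0. Of 18 tested members 11 rose, 2 fell and 5 did not pass, and 12 rose and 2 fell when adjusted over the list alone. The other member that fell was Lhx1 (-0.20 ± 0.070, adjusted p = 0.0355), whose call ended without the E14, E17, E18 or P0 array (highest adjusted p = 0.121, without P0), by exact rank correlation (0.0909) and with values under 5 set to 5 (0.363), as did that of Tbr1 by exact rank correlation (0.0535). The list passed upward (adjusted p = 0.00390), but not when the correlation was estimated (adjusted p = 0.421 with an estimated correlation), nor from E13 to P0 alone (adjusted p = 0.101). Over the same ages, the median level of the meninges and mesenchyme list was 6.95 at E11 and 9.24 at P0.

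Genes of the GABAergic lineage, which gives the granule and periglomerular interneurons of the bulb, rose in most cases. Gad1, the enzyme that makes GABA, had a slope of 0.42 ± 0.062 (adjusted p = 0.000413) and read 10.76 at E11 and 13.13 at P0, 5.16-fold higher. Th, the rate-limiting enzyme of dopamine synthesis in a class of periglomerular cells, had a slope of 0.50 ± 0.040 (adjusted p = 1.27e-05) and read 6.37 at E11 and 10.12 at P0, 13.4-fold higher. The interneuron factors Dlx1 (0.23 ± 0.049), Dlx2 (0.13 ± 0.025) and Sp8 (0.16 ± 0.033) rose by less. The steepest rises were those of Synpr, a synaptic vesicle protein (0.76 ± 0.11), Prokr2, a receptor of migrating neuroblasts (0.54 ± 0.12), and the neuropeptide gene Trh (0.53 ± 0.063). The Prokr2 call ended by exact rank correlation (adjusted p = 0.0535). Of 27 tested members 18 rose, 2 fell and 7 did not pass, and 19 rose and 2 fell when adjusted over the list alone. The 2 that fell were Isl1 (-0.88 ± 0.14) and Gsx2, a homeobox factor of ventral progenitors (-0.50 ± 0.060). The list passed upward (adjusted p = 0.00302), but not when the correlation was estimated (adjusted p = 0.297 with an estimated correlation). The median level of the GABAergic list was 9.51 at E11, 8.21 at E12, 8.72 at E15, 9.43 at E18 and 10.12 at P0. It lay above its E11 level at P0 only, so that the list did not rise evenly. The median of the ensheathing cell list was 4.89 at E11 and 8.87 at P0 on the same arrays.

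Genes of the synapse rose almost without exception. Of 30 tested members 27 rose, 0 fell and 3 did not pass, and 28 rose and 0 fell when adjusted over the list alone. Syn2, a synapsin of synaptic vesicles (0.95 ± 0.16), Gria1, a subunit of AMPA receptors (0.85 ± 0.17), Camk2b, a calcium-dependent kinase (0.63 ± 0.10), and Gabrb2, a subunit of the GABA receptor (0.62 ± 0.086), were the steepest. The median level of the list was 5.60 at E11, 9.55 at E15 and 9.78 at P0. Camera gave adjusted p = 1.27e-08, and adjusted p = 0.351 with an estimated correlation. On the same arrays the median of the microglia list was 5.15 at E11, 7.65 at E15 and 7.94 at P0. Genes of axon growth and neuronal migration were more mixed, and of 31 tested 15 rose, 4 fell and 12 did not pass, and 16 rose and 4 fell when adjusted over the list alone. Cntn1, an adhesion molecule of axons (0.74 ± 0.10), and Unc5c, a netrin receptor (0.51 ± 0.12), rose most, while Dcc, another netrin receptor (-0.25 ± 0.030), fell. The Unc5c call ended by exact rank correlation (adjusted p = 0.0535) and from E13 to P0 alone (0.0845). The list of axon genes passed at adjusted p = 0.0443 and lost its call with adjusted p = 0.582 with an estimated correlation, without the E11 array (adjusted p = 0.579), with embryo sex in the fit (0.0670), without probe sets that can match several transcripts (0.0604) and from E13 to P0, where its direction turned (adjusted p = 0.507).

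**Figure D1:**
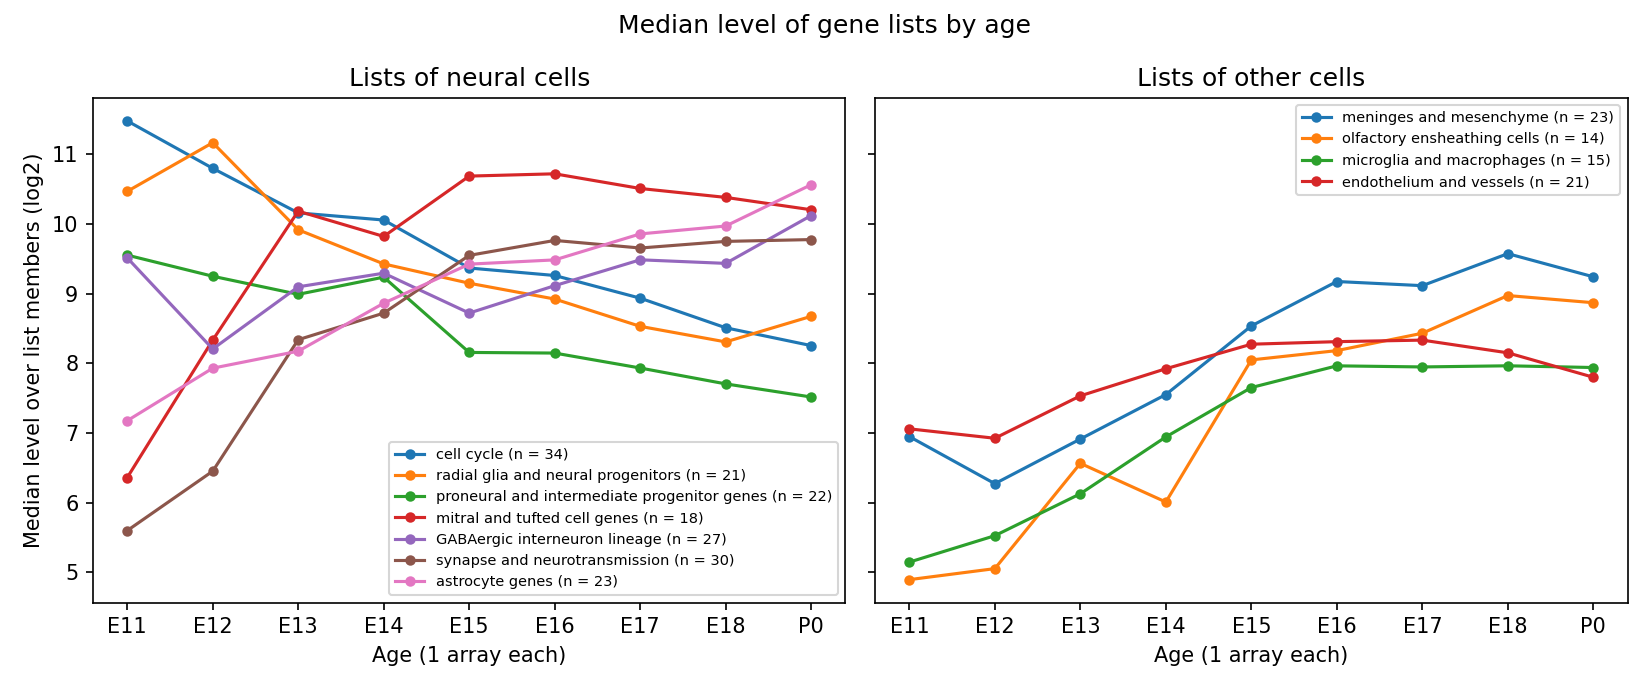
Median log2 level over the members of 11 gene lists (vertical axis) at each of the 9 ages (horizontal axis, 1 array each, no error bars since no age had a replicate), with lists of neural cells on the left and of other cells on the right. The cell cycle list stands at 11.48 at E11 and 8.25 at P0, and the synapse list at 5.60 and 9.78.

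Most genes of astrocytes and of the oligodendrocyte lineage rose. Of 23 tested astrocyte genes 20 rose, 2 fell and 1 did not pass, and 20 rose and 2 fell when adjusted over the list alone. Bcan (1.03 ± 0.070), Tnc, a matrix glycoprotein (0.93 ± 0.11), Apoe, a lipid carrier (0.66 ± 0.048), and Slc4a4, a bicarbonate transporter (0.70 ± 0.094), rose. Aldh1l1, a folate enzyme of astrocytes, rose by 0.90 ± 0.22, and its call ended without the E11 array (adjusted p = 0.0520). Id4 (-0.30 ± 0.034) and Hopx (-0.24 ± 0.070), which are also expressed in progenitors, fell, and the Hopx call ended without the E12 array (adjusted p = 0.0571), by exact rank correlation (0.170) and from E13 to P0 alone (0.202). The astrocyte list was the 1 list of 33 that passed both with the preset correlation (adjusted p = 1.57e-06) and with an estimated one (adjusted p = 0.0462 with an estimated correlation). Of 12 tested genes of the oligodendrocyte lineage 8 rose, 1 fell and 3 did not pass, and 8 rose and 1 fell when adjusted over the list alone. Olig1, a factor of oligodendrocyte precursors, read 5.74 at E11, 2.79 at E13 and 9.93 at P0 (slope 0.81 ± 0.14), and Pdgfra, the growth factor receptor of these precursors and of mesenchyme, had a slope of 0.56 ± 0.12. Opcml (0.73 ± 0.12) and Lhfpl3 (0.63 ± 0.14) rose too. Olig2, the partner of Olig1, had a slope of 0.091 ± 0.11 (adjusted p = 0.526), and without the E11 array a slope of 0.29 (adjusted p = 0.00835), and it also passed from E13 to P0 alone (0.0140). The oligodendrocyte list passed with the preset correlation (adjusted p = 0.0207) but not otherwise (adjusted p = 0.240 with an estimated correlation).

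Genes of olfactory ensheathing cells, the glia that accompany the olfactory nerve, had the largest median change of the lists tested, 4.79 log2 units over the course. The median level of the list at E11 was 4.89, under the filter level of 5, so that the size of this change rests in part on readings under that level. Of 14 tested 13 rose, 0 fell and 1 did not pass, and 13 rose and 0 fell when adjusted over the list alone. Npy (1.02 ± 0.14), the protease Prss56 (0.79 ± 0.092), the Wnt antagonist Frzb (0.71 ± 0.11) and the integrin Itga7 (0.64 ± 0.079) rose most. Camera gave adjusted p = 1.15e-06, and adjusted p = 0.297 with an estimated correlation. Among genes of olfactory sensory neurons and the nasal epithelium, 5 of 11 rose, 3 fell and 3 did not pass, and 6 rose and 3 fell when adjusted over the list alone. The filter left out 13 of the 28 genes on this list, Omp, Cnga2 and Cnga4 among them. The G protein subunits Gnal (0.67 ± 0.10) and Gng13 (0.50 ± 0.090), which also serve neurons of the brain or other sense organs, and the mitochondrial creatine kinase Ckmt1 (0.67 ± 0.086) rose, and Lhx2, a factor shared with forebrain progenitors (-0.38 ± 0.050), fell. This list did not pass (adjusted p = 0.282, and adjusted p = 0.421 with an estimated correlation).

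Markers of the brain coverings and of immune cells mostly rose on the same arrays. Of 23 tested genes of meninges and mesenchyme 17 rose, 0 fell and 6 did not pass, and 18 rose and 1 fell when adjusted over the list alone. Ogn (1.11 ± 0.11), Slc6a13 (1.08 ± 0.12), the proteoglycan Dcn (0.89 ± 0.13) and the collagen Col6a1 (0.85 ± 0.13) were the steepest, and Dcn read 6.69 at E11 and 12.30 at P0. Camera gave adjusted p = 5.61e-06, and adjusted p = 0.408 with an estimated correlation. Of 15 genes of microglia and macrophages 14 rose, 0 fell and 1 did not pass, and 15 rose and 0 fell when adjusted over the list alone. The complement genes C1qc (0.60 ± 0.060) and C1qa (0.53 ± 0.058) rose, as did Lyve1 (0.56 ± 0.091) and Mrc1 (0.54 ± 0.080), markers of macrophages at the brain borders. That list gave adjusted p = 1.57e-06, and adjusted p = 0.297 with an estimated correlation. Genes of the endothelium and vessels rose less uniformly, since of 21 tested 10 rose, 1 fell and 10 did not pass, and 10 rose and 1 fell when adjusted over the list alone. The mural cell gene Rgs5 (0.60 ± 0.10), Vtn (0.59 ± 0.060), and the genes of the blood-brain barrier Abcb1a (0.49 ± 0.051) and Cldn5 (0.35 ± 0.048) rose. Those that did not pass included Kdr (0.040, adjusted p = 0.542), Egfl7 (0.034, adjusted p = 0.474), Eng (0.036, adjusted p = 0.431) and Sox18 (0.025, adjusted p = 0.661). The endothelial list passed with the preset correlation (adjusted p = 0.00155) and not otherwise (adjusted p = 0.421 with an estimated correlation).

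Embryonic globins fell among the red cell genes. Of 8 tested members 0 rose, 4 fell and 4 did not pass, and 0 rose and 4 fell when adjusted over the list alone. Hbb-y read 14.48 at E14, 11.37 at E15 and 5.48 at E16. Slc4a1, the anion exchanger of the red cell membrane, fell with a slope of -0.62 ± 0.10. Alas2, the erythroid enzyme of heme synthesis, had a slope of -0.10 ± 0.076 (adjusted p = 0.306) and did not pass. The list passed with the preset correlation (adjusted p = 0.0160) but not otherwise (adjusted p = 0.306 with an estimated correlation), nor without the E11 array (adjusted p = 0.0558), without probe sets that can match several transcripts (0.139) or from E13 to P0 alone (0.101). Few genes of the other neighbouring tissues were tested. The filter left out 21 of 24 muscle genes and 21 of 24 genes of surface ectoderm and respiratory epithelium. It also left out 13 of 22 genes of cartilage and bone and 7 of 10 of pigment cells. All 3 tested muscle genes rose, Myh7 (0.60 ± 0.14) and Myh8 (0.40 ± 0.068) most, but their list did not pass (adjusted p = 0.0573, and adjusted p = 0.302 with an estimated correlation), except without the E17 array (adjusted p = 0.0383), with embryo sex in the fit (0.0351), with P0 at day 20 (0.0476) and from E13 to P0 alone (0.0396). Adjusted over the list alone, all 3 rose. The Myh7 call ended from E13 to P0 alone (adjusted p = 0.0602). Of 6 genes of cartilage and bone 2 rose, 1 fell and 3 did not pass, and 2 rose and 1 fell when adjusted over the list alone, with Matn4 (0.93 ± 0.12) up and Col2a1 (-0.41 ± 0.069) down (adjusted p = 0.485, and adjusted p = 0.637 with an estimated correlation). Of 3 genes of surface ectoderm and respiratory epithelium 2 rose, 1 fell and 0 did not pass, and 2 rose and 1 fell when adjusted over the list alone, with Perp, a desmosome protein (0.47 ± 0.068), the steepest (adjusted p = 0.421, and adjusted p = 0.490 with an estimated correlation). Of 3 genes of pigment cells 2 rose, 1 fell and 0 did not pass, and 2 rose and 1 fell when adjusted over the list alone. Dct (-0.72 ± 0.11) fell and Mitf (0.44 ± 0.033) rose, the median slope was 0.12, the mean slope was -0.052 and the test pointed upward without passing (adjusted p = 0.431, and adjusted p = 0.490 with an estimated correlation).

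Genes of the ribosome and of respiration moved by small amounts. Of 43 tested genes of ribosomal proteins 0 rose, 13 fell and 30 did not pass, and 0 rose and 8 fell when adjusted over the list alone. Rpl14 had the steepest slope (-0.31 ± 0.043), and the median change of the list was -0.23 log2 units (adjusted p = 0.000724, and adjusted p = 0.421 with an estimated correlation). Rpl7l1 had a slope of -0.19 ± 0.020 on the probe set used and another probe set of opposite sign, and its call ended with the mean of its probe sets (adjusted p = 0.709). Of 69 genes of oxidative phosphorylation 21 rose, 0 fell and 48 did not pass, and 20 rose and 0 fell when adjusted over the list alone. Atp5g1 (0.13 ± 0.036) and Ndufa5 (0.13 ± 0.030) rose most, with a median change of 0.32 over the list (adjusted p = 0.000555, and adjusted p = 0.490 with an estimated correlation). From E13 to P0 alone the calls of Atp5g1 (adjusted p = 0.151) and Ndufa5 (0.199) ended, that of Ndufa5 also by exact rank correlation (0.0909).

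Signalling genes split between rising and falling members. Among 26 genes of FGF, BMP, Shh and retinoid signalling 14 rose, 8 fell and 4 did not pass, and 14 rose and 9 fell when adjusted over the list alone. The ligands Bmp6 (0.94 ± 0.095) and Bmp5 (0.92 ± 0.11) and Aldh1a2, which makes retinoic acid in the meninges (0.81 ± 0.076), rose. Fgf15, a ligand of early forebrain progenitors (-0.54 ± 0.057), and Gli3, a transcription factor of the Shh pathway (-0.53 ± 0.038), fell. That list did not pass (adjusted p = 0.308, and adjusted p = 0.493 with an estimated correlation). Among 21 Wnt genes 4 rose, 8 fell and 9 did not pass, and 4 rose and 8 fell when adjusted over the list alone, with the ligand Wnt5a (0.55 ± 0.090) and the receptor Fzd7 (0.41 ± 0.046) up and the receptor Fzd8 (-0.49 ± 0.047) and the antagonist Sfrp1 (-0.33 ± 0.036) down (adjusted p = 0.323, and adjusted p = 0.453 with an estimated correlation). Among 13 immediate early and stress genes 6 rose, 4 fell and 3 did not pass, and 6 rose and 4 fell when adjusted over the list alone. Fos (0.69 ± 0.057) and Egr1 (0.48 ± 0.087), which respond to neuronal activity and to handling of tissue, rose (adjusted p = 0.334 for the list, and adjusted p = 0.421 with an estimated correlation). Among 9 heterochronic and early embryonic regulators 1 rose, 4 fell and 4 did not pass, and 1 rose and 4 fell when adjusted over the list alone. Igf2bp3, an RNA-binding protein of embryonic tissue (-0.45 ± 0.026), fell and the growth factor Igf2 (0.43 ± 0.054) rose (adjusted p = 0.107 for the list, and adjusted p = 0.306 with an estimated correlation). The FGF, BMP, Shh and retinoid list passed from E13 to P0 alone (adjusted p = 0.0449), the immediate early list without a filter (0.0254), and the heterochronic list without a filter (0.0190) and without probe sets that can match several transcripts (0.0267). In all, 11 lists passed upward and 6 downward with the preset correlation. In 8 of 100 orders of the ages, the real one included, at least as many lists passed, and the other orders had a median of 10.

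Transcription factors, the subject of the series, were more often among the falling genes than other genes were. Of 628 tested, 169 fell (26.9%) against 21.6% of other genes (odds ratio 1.33, p = 0.00241, Fisher's exact test, two-sided). Fewer rose, 101 of 628 (16.1%) against 25.8% of other genes (odds ratio 0.551, p = 1.55e-08, Fisher's exact test). Adjusted over the list alone, 97 rose and 163 fell. The lower share among rising genes was not kept when the zinc finger Zfp genes were counted among the other genes instead, a setting chosen after the data were seen. In that setting 84 of 361 factors rose (odds ratio 0.895, Fisher's exact p = 0.423) and 116 fell (odds ratio 1.72, Fisher's exact p = 5.23e-06). All these Fisher's tests were across genes, which are not independent replicates, and their p-values do not measure the spread between animals. The shares of factors were not counted in the other orders of the ages. As a list against all other genes, the factors did not pass (adjusted p = 0.0637, and adjusted p = 0.408 with an estimated correlation), except without the E11 (adjusted p = 0.0244) or E17 array (0.0480), with embryo sex in the fit (0.0369), without probe sets that can match several transcripts (0.0437) and from E13 to P0 alone (0.0247).

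The factors with the steepest falls were Hmga2 (-1.29 ± 0.080), Isl1 (-0.88 ± 0.14), Stat4 (-0.82 ± 0.17), Neurog1 (-0.72 ± 0.064), Nhlh1 (-0.64 ± 0.073), Dmrta1 (-0.63 ± 0.052), Sall4 (-0.62 ± 0.047) and Nr2e1 (-0.60 ± 0.056). Dmrta1, a doublesex-related factor of early pallial progenitors, read 9.77 at E11 and 5.81 at P0. Sall4, a zinc finger factor of pluripotent cells, read 7.51 at E11 and 2.82 at P0. Stat4, a transducer of cytokine signals, read 9.06 at E11, 4.88 at E13 and 2.28 at P0. Those with the steepest rises were Tbx21 (0.82 ± 0.079), Olig1 (0.81 ± 0.14), Zfp385b (0.71 ± 0.13), Fosl2 (0.70 ± 0.055), Fos (0.69 ± 0.057), Lmo3 (0.66 ± 0.12), Egr3 (0.65 ± 0.091) and Tshz2 (0.64 ± 0.10). Fosl2 and Egr3 belong, with Fos, to the factors induced by neuronal activity, and Lmo3 is a LIM-only cofactor of neurons. Each of these calls held with any single array left out, except that Stat4 failed the filter, and so was not tested, without E11 or E12. The meninges and mesenchyme list had a median of 6.95 at E11 and 9.24 at P0 over the same course.

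**Figure D2:**
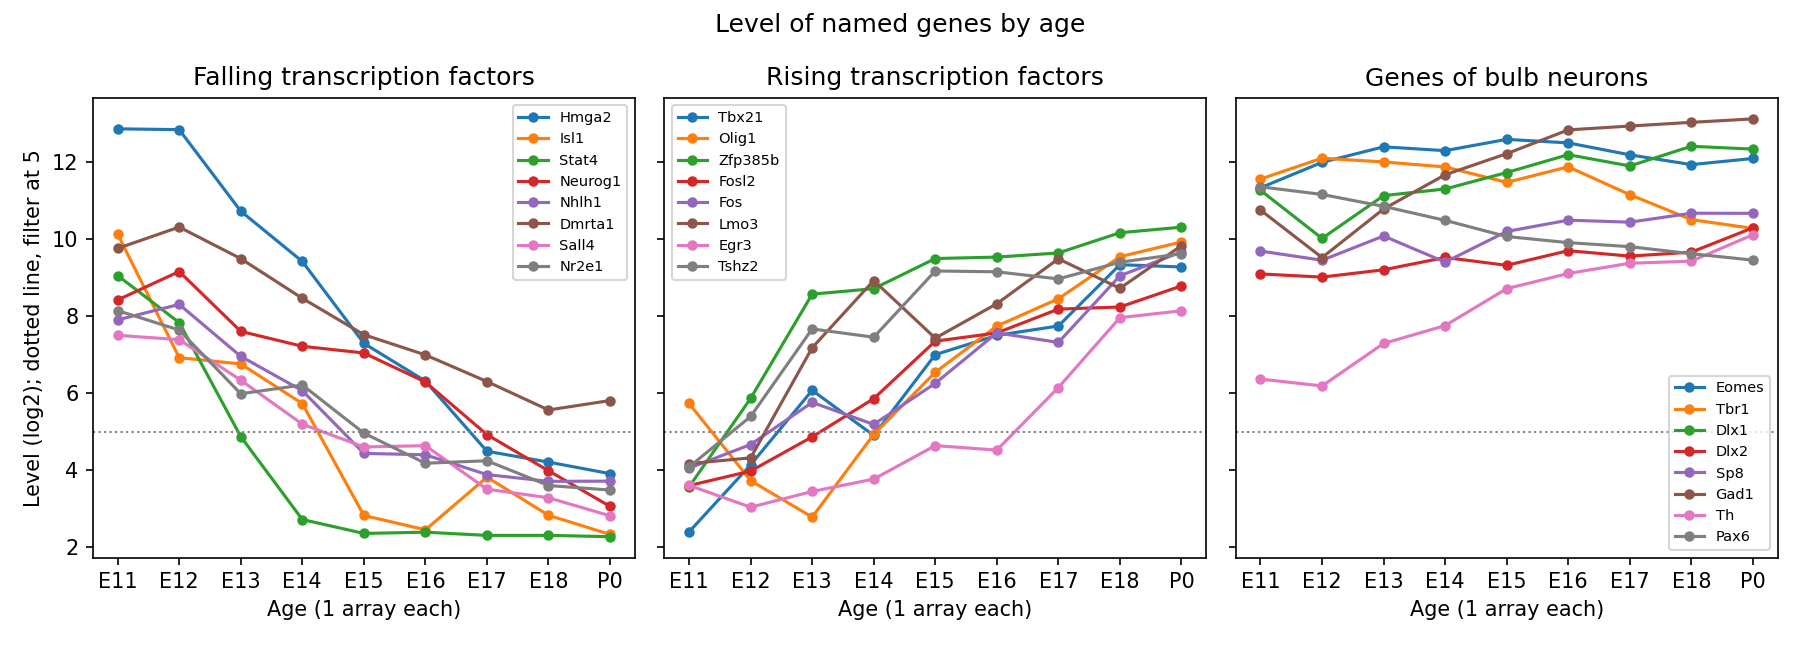
Log2 level (vertical axis) of 8 falling factors, 8 rising factors and 8 genes of bulb neurons or their progenitors at each of the 9 ages (horizontal axis, 1 array each, no error bars since no age had a replicate), with a dotted line at the filter level of 5. Hmga2 reads 12.87 at E11 and 3.92 at P0, while Eomes stays between 11.34 and 12.60.

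Families of factors held rising and falling members. Of 48 homeobox factors 14 rose, 19 fell and 15 did not pass, and 14 rose and 22 fell when adjusted over the list alone, with Isl1 (-0.88 ± 0.14) and Otx2 (-0.57 ± 0.076) steepest downward and Tshz2 (0.64 ± 0.10) upward (adjusted p = 0.0799, and adjusted p = 0.306 with an estimated correlation). Of 31 Sox and Fox factors 7 rose, 9 fell and 15 did not pass, and 7 rose and 9 fell when adjusted over the list alone. Sox3 fell (-0.58 ± 0.070), and Foxc2 (0.51 ± 0.092) and Foxd1 (0.49 ± 0.10), both factors of mesenchyme and meninges, rose (adjusted p = 0.937, and adjusted p = 0.967 with an estimated correlation). Of 46 basic helix-loop-helix and Id factors 12 rose, 13 fell and 21 did not pass, and 12 rose and 13 fell when adjusted over the list alone. Neurog1 (-0.72 ± 0.064) and Olig1 (0.81 ± 0.14) lay at the extremes, and the median slope of 0.0021 and the mean slope of 0.0022 were above 0 while the test pointed downward (adjusted p = 0.646, and adjusted p = 0.679 with an estimated correlation). Of 18 nuclear receptors 10 rose, 4 fell and 4 did not pass, and 10 rose and 4 fell when adjusted over the list alone, with Nr2e1 (-0.60 ± 0.056) down and Rora (0.64 ± 0.068) and Esrrg (0.39 ± 0.051) up (adjusted p = 0.141, and adjusted p = 0.306 with an estimated correlation). Of 267 Zfp genes 17 rose, 53 fell and 197 did not pass, and 13 rose and 42 fell when adjusted over the list alone. Zfp385b (0.71 ± 0.13) and Zfp704 (0.39 ± 0.048) rose against a median change of -0.19 (adjusted p = 0.0312 downward, and adjusted p = 0.421 with an estimated correlation), and the list lost its call without the E18 (adjusted p = 0.0891) or P0 array (0.0681). Of the 218 remaining factors 41 rose, 71 fell and 106 did not pass, and 41 rose and 71 fell when adjusted over the list alone. Hmga2 (-1.29 ± 0.080) and Tbx21 (0.82 ± 0.079) lay at the extremes (adjusted p = 0.107, and adjusted p = 0.425 with an estimated correlation), and this list passed without the E11 array (adjusted p = 0.0401). Without a filter the homeobox list (adjusted p = 0.0426) and the list of nuclear receptors (0.0178) passed.

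Curved courses were mostly rises that levelled off. Cntn3, an adhesion molecule of neurons, read 2.63 at E11, 9.82 at E16 and 8.15 at P0, and the fitted peak lay 4.52 log2 units (adjusted p = 0.00315) above the mean of the fitted ends. Its linear call ended without the E11, E12, E16, E17 or E18 array (highest adjusted p = 0.288, without E11), and likewise with embryo sex in the fit (0.0645), with P0 at day 20 (0.0661), without a filter (0.0879), without the variance trend (0.0511), with values under 5 set to 5 (0.0504), from E13 to P0 alone (0.514) and by exact rank correlation (0.470). Eomes read 11.34 at E11, 12.60 at E15 and 12.10 at P0, with a peak of 0.82 log2 units (adjusted p = 0.0214). The other genes among the 8 largest peaks were Aldh1l1, with 4.77 log2 units (adjusted p = 0.0411), Gabrg1, a GABA receptor subunit, with 4.66 log2 units (adjusted p = 0.0270), Cpne6, with 4.65 log2 units (adjusted p = 0.00328), Sla, with 4.27 log2 units (adjusted p = 0.0239), Syn2, with 4.26 log2 units (adjusted p = 0.0158), Nwd2, with 4.23 log2 units (adjusted p = 0.0238), and Gria1 (adjusted p = 0.0127). Cpne6, Syn2, Gria1 and Aldh1l1 had their highest value at P0. In all 476 genes peaked between the ends of the course in the fit, and 363 of them also had a rising linear trend. A stricter meaning of a peak was chosen after the data were seen. It asked that the mean of E11 and E12 and the mean of E18 and P0 both lie at least 1 log2 unit below the highest mean of 3 consecutive ages, and 10 genes met it. Among these, Neurod6, a factor of differentiating glutamatergic neurons, read 8.51 at E11, 12.41 at E14 and 9.86 at E18 (adjusted p = 0.0249), and the Wnt inhibitor Wif1 read 3.18, 6.03 and 3.85 at E11, E13 and E18 (adjusted p = 0.0407). Both were picked after their values were seen.

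Courses that dipped included early losses and late gains. Hbb-bh1 read 14.26 at E11 and 2.89 at E15 with a quadratic change of -6.56 log2 units (adjusted p = 0.00328), and Stat4 (quadratic change of -4.19, adjusted p = 0.00783) and Fndc3c1 (-4.21, adjusted p = 0.0142) had a like course. Crh, a neuropeptide, read at most 3.39 up to E16 and 9.04 at P0 (-3.62, adjusted p = 0.0270), and Mgp, a matrix protein of vessels and cartilage, read 2.91 at E15 and 8.74 at P0 (-3.60, adjusted p = 0.0391). In all 121 genes dipped in the fit, of which 54 also fell and 13 also rose in the linear fit. The mean of E11 and E12 and the mean of E18 and P0 were both at least 1 log2 unit above the lowest mean of 3 consecutive ages for 11 genes, among them Lamb2, a laminin (adjusted p = 0.0375), the metallothionein Mt1 (adjusted p = 0.0407) and the lactate transporter Slc16a1 (adjusted p = 0.0139), picked after their values were seen. With embryo sex in the fit, 67 genes peaked and 6 dipped, and without the E11 array the counts were 147 and 22. Peaks also numbered 196 without E15, 267 without E16 and 261 without E18, and dips 65 without E14, 29 without E15, 72 without E16, 50 without E18 and 80 without P0. Of the 19 peaks and dips named here, 16 lost their call with embryo sex in the fit, 12 without a filter, 8 with P0 at day 20, 3 without the variance trend and 1 with values under 5 set to 5. The calls of Cpne6, Cntn3 and Hbb-bh1 held in these settings, while those of Fndc3c1 (adjusted p = 0.0854) and Stat4 (0.0510) were lost with embryo sex, and P0 at day 20 gave adjusted p = 0.0963 for Crh and 0.213 for Mgp. Cpne6, Cntn3 and Hbb-bh1 also held with any single array left out. Fndc3c1 and Stat4 failed the filter without E11 or E12, the arrays on which their dips rest, and were not tested there, while leaving out 1 array gave an adjusted p as high as 0.118 for Aldh1l1 (E11), 0.0793 for Gabrg1 (E15), 0.0678 for Sla (E15), 0.0532 for Syn2 (E15), 0.0731 for Nwd2 (E15), 0.0508 for Gria1 (E11), 0.0784 for Crh (E15), 0.110 for Mgp (E15) and, without E11, 0.161 for Eomes, 0.207 for Wif1, 0.179 for Lamb2, 0.134 for Mt1 and 0.0962 for Slc16a1. The Neurod6 peak was lost without E11 as well.

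Between consecutive ages, the levels differed most up to E15. From E12 to E13, 779 genes were at least 2-fold higher and 267 at least 2-fold lower at the later age. Tbx21 read 4.15 at E12 and 6.08 at E13, and Zfp385b read 5.87 and 8.58. From E11 to E12, 522 genes were higher and 309 lower, among them Isl1, which read 10.14 and 6.93. From E14 to E15, 608 genes were higher and 162 lower, among them Bcan, which read 5.62 and 8.03, and Gda, which read 5.78 and 8.96. The steps from E13 to E14, E15 to E16, E16 to E17 and E17 to E18 held 374, 248, 272 and 246 such genes, and the step from E18 to P0 held 138. These counts compare single arrays and carry no test. The steps at E12 to E13 and E14 to E15 joined animals of different sex, as did E15 to E16 and E18 to P0. The spike-in controls read 10.38 at E15 and between 9.66 and 9.94 on the other arrays.

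**Figure D3:**
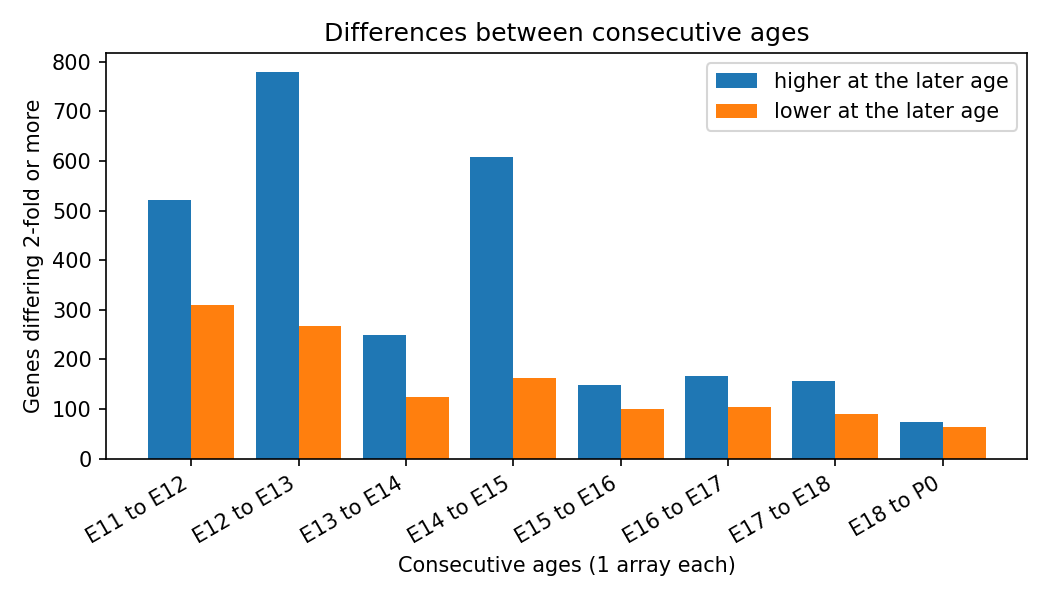
Number of genes (vertical axis) that were at least 2-fold higher or lower at the later of 2 consecutive ages (horizontal axis), from single arrays and without a test. The step from E12 to E13 holds 1046 genes in all and the step from E18 to P0 holds 138.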

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

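In this part, the tests of signal level, of embryo sex, of separate sets of arrays, of the share of neural cells and of a fixed makeup were chosen only after the result was seen.

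Probe sets with several gene names or none, which no comparison of the results used, also carried trends, with 394 rising and 1074 falling among 3158. Falling trends made up 73.2% of their calls against 49.9% for probe sets with 1 name. Probe sets of named genes matched to them on level had a share of 47.2% on average over 1000 draws (lowest 43.3%, highest 51.5%), which argues against their lower signal. With the actin difference between 3' and 5' probe sets as a covariate the share was 77.0%, which argues against a drift of RNA quality that actin follows. The same difference for Gapdh had a slope of 0.045 log2 units per day, against 0.034 for actin, and was not used as a covariate. The age of the animals stays open as a biological explanation and was not tested apart from these.

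The steps from E12 to E13, E11 to E12 and E14 to E15 held the most 2-fold differences (1046, 831 and 770). A change of embryo sex as the whole cause is argued against by the step from E18 to P0, between the sexes, which held 138 genes against at least 246 in the steps within a sex, E11 to E12 among them. A disturbed E13 or E15 array is argued against as well, since 86.8% of the differences at E13 kept at least 0.5 of their size at E14, and 87.9% of those at E15 did so at E16. For E12 this share was 80.7%, which by the same rule argues against a disturbed E12 array too, though it lies below the shares of E13 and E15. For E14 it was 66.8%, for E16 66.5%, for E17 72.4% and for E18 75.2%, and a disturbance of each of these arrays stays open. Arrays processed in separate sets cannot be told apart from age, because normalization removes a common shift and the labels give no date, and the spike-in controls differed by -0.019 log2 units between E13 to E14 and E11 to E12. At the step from E14 to E15 these controls read 9.73 and 10.38, the latter the highest of all arrays.

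Markers of meninges, ensheathing cells and macrophages rose beside the neural genes, for instance Dcn to 12.30 and Ptgds to 13.74 at P0. A falling share of neural cells alone would raise the lists of other cells alike, but the median change of 20 endothelial genes on neither of the lists compared lay -2.43 log2 units from that of the meninges list (permutation p = 0.00299) and -3.40 from that of the ensheathing cell list (permutation p = 0.000560). Both permutations were across genes, which are not independent replicates, and their p-values do not measure the spread between animals. Of 21 meninges genes at log2 7 or more at E15, 11 had a 95% interval of the slope from E15 to P0 that left out the list's median slope. The slopes ran from -0.213 for Tbx18 to 0.619 for Ogn. Such a spread argues against a single added tissue of fixed makeup only where the bulb itself expresses none of these genes. Zic1, 1 of the 11, is also on the list of the GABAergic lineage, so that this test cannot decide. Of the 23 meninges genes 8 were on another list too, and for the endothelial list these were 5 of 21. How much covering tissue came with each bulb, and growth of these tissues with age, stay open and were not tested.

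Orders of the 9 ages drawn at random were fitted in the same way, 100 in all with the real one. Chance is argued against for the number of genes with a linear trend, with 5125 genes in the real order and at most 2632 in another (1 of 100 orders as large). That is the smallest share that 100 orders can give, and it bears on the count and not on single genes. For the peaks and dips together in the fit without embryo sex, 597 genes were called (2 of 100 orders as large, the real one included). This cannot decide about chance, because a drawn order also breaks the linear trend with age, which then counts as scatter. The other such order called 4529 genes, several times the real count, and the cause of this was not tested. With embryo sex in the fit 67 genes peaked and 6 dipped, 3 of the 4 female arrays lie at the ends of the course, and the orders were not run with sex in the fit. Chance cannot be excluded for the number of gene lists that pass with the preset correlation, 17 in the real order against up to 20 in another (8 of 100 orders as large). The other orders had a median of 10 lists, so that many lists pass with the preset correlation in drawn orders too.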

How the results depend on the processing

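Tests of a floor at log2 5, of E13 to P0 alone, of the stricter meaning of peaks and dips and of the list without Zfp genes were chosen only after the data were seen. Of 165 named genes 149 were called, and 120 of these kept their direction and call under each alternative in which they were tested. With values under 5 set to 5, 2625 of 2743 rising and 2314 of 2382 falling genes kept their call. From E13 to P0, 1529 genes rose and 1193 fell, 1400 and 1055 of them as before, with fewer arrays. In that fit the slopes of Cntn3 (-0.080), Dsp (-0.0058), Sema3a (-0.026), Neurod6 (-0.33) and Wif1 (-0.41) turned, as did the axon list (adjusted p = 0.507). Falling genes numbered 1506 at an adjusted p of 0.01 and 1240 with a 2-fold minimum, by construction of the thresholds. Leaving out each array in turn gave 2223 to 2758 rising, 1788 to 2332 falling, 147 to 474 peaking and 22 to 105 dipping genes. Peaks numbered 67 with embryo sex as a covariate, 213 without a filter, 271 with P0 at day 20 and 10 in the stricter meaning, and dips numbered 6 with embryo sex, 80 with P0 at day 20 and 11 in the stricter meaning. With an estimated correlation 1 list rose and 0 fell. With the Zfp genes counted among the other genes, the odds ratio of factors among rising genes was 0.895 and no longer passed. At 4-fold, 553 differences between consecutive ages were left of 3925 (91, 244, 43, 99, 22, 25, 18 and 11 by step), by construction, and without a filter the step from E18 to P0 held 253. Where no construction is named, the cause was not tested.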

Other observations

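All gene families in this part were tested only after the data were seen, while the test of when genes rise was planned before its result was seen.

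Genes were also grouped by a shared symbol stem, and some of these families, the collagens among them, overlap the fixed lists. Of 272 families with at least 6 tested members, 18 passed upward and 28 downward with the preset correlation, and 0 with an estimated one (lowest adjusted p = 0.540 with an estimated correlation). Nucleoporins fell, with 16 of 18 Nup genes falling and a median change of -1.23 log2 units over the course. Of the Ints genes of the Integrator complex 11 of 15 fell, of the Polr genes of RNA polymerases 12 of 25, and of the Ddx genes of RNA helicases 15 of 31. Metabotropic glutamate receptors rose in all 6 Grm genes tested, with a median change of 4.55. Of the Camk genes of calcium-dependent kinases 8 of 10 rose, of the collagens 16 of 26 rose and 2 fell, and of the Pcdhb genes of clustered protocadherins 7 of 9 rose.

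Rising genes may rise in an order, with synapse genes before genes of meninges and astrocytes. Each rising gene of these lists with a difference of at least 1 log2 unit was given the age at which it first reached the middle between its mean at E11 and E12 and its mean at E18 and P0. The median age was 12.8 days for 25 synapse genes and 14.2 days for 36 genes of meninges and astrocytes, 1.47 days later (permutation p = 0.000310 across genes, which are not independent replicates). The order rests on 9 animals, 1 per age.

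The 4 probe sets shared by several adult globin genes read between 13.26 and 14.88 on all arrays, except for 1 that read 10.75 at E13, while the embryonic globin Hbb-y read 15.52 at E11 and 2.90 at P0.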
